A study of Homo sapiens with 4 samples.

How the data were processed

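PLC8024 is a human hepatocellular carcinoma cell line. Per the labels, its cells were sorted by flow cytometry into a CD133+ and a CD133- population, total RNA was extracted with Trizol, and biotin-labelled RNA was made with an Ambion MessageAmp II kit. The 4 deposited samples are 1 CD133+ and 1 CD133- population, each given in 2 processings of the array values. The MAS5 samples hold linear intensity values that the authors deposited as MAS5 output, and the RMA samples hold log2 values that the authors deposited as RMA output. GCOS, MAS5 and RMA are named in the submitters' processing notes, and their versions are not given in the sources used here. Which arrays were normalized together, and whether the MAS5 and RMA columns of a population come from the same array, is not given in the sources used here either. The RMA and MAS5 columns were therefore treated as 2 processings and never as replicates, so that each population had 1 value per processing.

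Each column held 54675 probe sets with no missing value. The 2 MAS5 columns had means of 500.1 after the lowest and highest 2% of values were trimmed, which is the form of MAS5 global scaling. Their medians were 86.0 in the CD133+ and 86.1 in the CD133- column. The RMA columns had medians of 5.16 and 5.14 and maxima of 14.2 in both. The files used here held no detection calls, so an expression floor took their place. With 1 array per population in each processing, the number of arrays limits the precision of every difference, and no replicate check of any difference was possible.

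Probe sets were named from GEO's platform annotation for the array, and 41043 probe sets received a current symbol through their gene ID in a RefSeq gene table of assembly GRCh38.p14. Of the 54675 probe sets, 41097 had 1 gene, 1801 had several genes and 11777 had none or were not listed. Probe sets with several genes or none were given no gene name. A gene was represented by the probe set with the highest mean RMA value over both populations, which gave 19775 genes, 10523 of them with more than 1 probe set. No genome build is named for the array, so no coordinates are given, and the RefSeq table served for names and for the order of neighbouring genes.

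The difference of a gene was the RMA value in CD133+ minus that in CD133-, and the log2 of the MAS5 value in CD133+ over that in CD133- was its second measure. A gene was above the floor when the population with the higher RMA value reached the median of that column over all probe sets, which held for 13116 genes. A gene was counted as higher or lower in CD133+ when it was above the floor and differed by at least 2-fold in the same direction in RMA and in MAS5. Of the 64 named genes counted, 15 had their lower RMA value under the median of its column, that is, not above the floor in that population. For these no fold is given, and both log2 differences are. No test was run and no p-value is given, because genes and probe sets are not replicates. As a measure of technical spread, the differences of 2 probe sets of one gene were compared. This spread leaves out the variation between sorts, cultures and arrays.

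Gene lists were described by the median RMA difference of their members above the floor, and by the percentile of that median among 10000 random lists of the same size, matched on mean RMA value in 10 bins. A list outside the central 95% of random lists is said to stand apart from them, as a description of these arrays. The 32 lists were liver progenitor and tumour-initiating cell markers, mature hepatocyte genes, neurotensin, interleukin and CXC chemokine genes, NF-kappaB targets, drug efflux and detoxification genes, cancer-testis antigens, fatty acid and lipid metabolism genes, cholesterol synthesis genes, glycolytic enzymes, hypoxia-induced genes, secreted angiogenic factors and their regulators, Notch ligands, receptors and targets, Wnt/beta-catenin targets, TGF-beta targets, ERK/MAPK output and feedback genes, p53 targets, BCL2 family and caspase regulators, pluripotency and self-renewal factors, epithelial junction and keratin genes, mesenchymal genes, interferon-induced genes, G1/S and DNA replication genes, G2/M cell cycle genes, ribosomal protein genes, housekeeping genes, metallothioneins, immediate-early and heat-shock genes, unfolded protein and amino acid stress genes, and the markers of other cells: leukocyte markers, endothelial cell markers, fibroblast and stellate cell markers, and erythroid markers.

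The genes named in the text were set by a rule. They are PROM1, the gene of CD133; NTS, CXCL8, CXCL1, ANXA3 and TP53INP1, which earlier work on CD133+ liver tumour cells named; the 12 genes with the largest RMA difference in each direction among those counted; and in each list up to 4 members above the floor with the largest absolute RMA difference. Genes named outside this rule are said to have been chosen after their values were seen. The lists, the floor, the count rule, the naming rule and the alternatives not marked as added were fixed before the data were examined.

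The alternatives were MAS5 alone, MAS5 with a pseudocount of 50, no floor, a floor at the 75th percentile, the median over all probe sets of a gene, leaving out probe sets whose identifiers end in _x_at or _s_at, centring on the median, subtracting a loess trend on the mean level with a span of 0.3, thresholds of 1.5-fold and 3-fold, and RMA alone. The count rule was tested on simulated data with 19775 genes for the comparison of CD133+ with CD133-. It recovered 1 of 50 genes changed 1.5-fold, 20 of 50 changed 2-fold, 42 of 50 changed 3-fold and 47 of 50 changed 4-fold, and it counted 0 of 19575 unchanged genes. The simulation drew the noise of RMA and of MAS5 independently, each with an SD set from the spread between probe sets of one gene. In the data the 2 differences had a Pearson correlation of 0.652 across probe sets, and noise shared by both processings would pass both thresholds together. The 0 and the recovered shares therefore hold for the simulated setting only. Of 1000 simulated unchanged lists of 20 genes, 59 stood apart from random lists, and of 1000 lists shifted by 0.3 on the log2 scale, 987 did.

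The order of neighbouring genes was examined with the median RMA difference over windows of 50 neighbouring genes above the floor, against 1000 random gene orders. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.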

Results

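Gene expression was measured on oligonucleotide arrays in PLC8024 cells, a human hepatocellular carcinoma line, after sorting for CD133, a surface protein used to enrich tumour-initiating cells in liver cancer. There was 1 CD133+ and 1 CD133- population, each deposited as MAS5 intensities and as RMA log2 values, and no replicate, so no difference below carries an error between cultures or sorts. The values of the 2 populations had a Spearman correlation of 0.986 across probe sets in RMA and 0.920 in MAS5. Within a population the 2 processings had a correlation of 0.881 in CD133+ and 0.880 in CD133-, against 0.864 between MAS5 values of one population and RMA values of the other. The 3' over 5' ratios of the actin and GAPDH control probe sets were 1.04 and 0.907 in the CD133+ MAS5 column and 1.04 and 0.875 in the CD133- column.

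PROM1, which encodes CD133, was 19.9-fold higher in the CD133+ population, with RMA values of 10.35 against 6.04 on the log2 scale. Its MAS5 intensities were 5849 and 279.1, which is 21.0-fold. The array has 1 named probe set for this gene. The populations labelled CD133+ and CD133- thus differed in the sorted marker's transcript in the direction of their labels, and the difference ranked second among all genes counted as higher.

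Earlier work on CD133+ liver tumour cells named 5 further genes. CXCL1, which encodes a neutrophil-attracting chemokine, was 4.31-fold higher in CD133+, and NTS, which encodes the peptide neurotensin, was 3.02-fold higher from an RMA value of 11.80 in CD133-. ANXA3, which encodes a phospholipid-binding annexin, was 2.32-fold higher. CXCL8, which encodes interleukin-8, had an RMA difference of 0.93 and a MAS5 difference of 1.28, which misses the count rule in RMA, while its other probe set had an RMA difference of 1.52. TP53INP1, a p53-induced gene, had values of 7.01 in CD133+ and 7.06 in CD133-, and was not counted.

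Across the array, 295 genes were at least 2-fold higher and 143 at least 2-fold lower in CD133+ in both processings, which is 3.34% of the 13116 genes above the floor. Of the counted genes 67.4% were higher in CD133+. A difference of at least 4-fold in RMA was held by 82 of the higher and 35 of the lower genes. The central 95% of RMA differences ran from -0.78 to 0.96 around a median of 0.00. In 6170 genes with a second probe set above the floor, the RMA differences of the 2 probe sets had an SD of 0.35 around each other. A 2-fold difference in RMA thus exceeded this technical spread. In MAS5 the SD was 0.79, and the 95th percentile of the absolute gap between the 2 probe sets was 1.64. A 2-fold difference in MAS5 alone can therefore lie within that spread. Neither was set against any biological spread, which 1 array per population in each processing cannot give. Of the 167 counted genes with a second probe set above the floor, 165 had the same sign in that probe set. RMA and MAS5 differences had a Pearson correlation of 0.652 and a Spearman correlation of 0.703 across 28435 probe sets, which are not independent replicates.

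The largest difference in favour of CD133+ was that of IGFBP4, an insulin-like growth factor binding protein, which was 20.6-fold higher. LINC00473, a long noncoding RNA, had RMA values of 10.33 in CD133+ and 6.32 in CD133-. CACNA2D1, an auxiliary calcium channel subunit, had differences of 3.70 in RMA and 3.90 in MAS5 on the log2 scale, and its other probe set an RMA difference of 1.14. BID, a pro-apoptotic BCL2 family gene, had differences of 3.58 in RMA and 3.21 in MAS5, a lowest probe set difference of 1.5 and a median over its probe sets of 2.99. SERPINB9, a granzyme B inhibitor, was 11.1-fold higher with differences from 1.57 to 3.47. QPCT, a glutaminyl cyclase, SLITRK4, a neuronal membrane protein, and CDO1, the cysteine dioxygenase, had RMA differences of 3.46, 3.45 and 3.39 and MAS5 differences of 3.69, 2.90 and 2.83. The other probe sets of SLITRK4 and CDO1 were below the floor. In CACNA2D1, BID, QPCT, SLITRK4 and CDO1 the CD133- value was under the floor. HLA-DPA1 and HLA-DPB1, the chains of one MHC class II molecule, had RMA differences of 3.21 and 3.32 and MAS5 differences of 3.27 and 2.17. The lowest RMA difference among the probe sets of HLA-DPA1 was 2.09. UCHL1, a ubiquitin hydrolase abundant in neurons, was 9.47-fold higher. For HLA-DPB1 and UCHL1 the probe sets left without the _s_at ones were below the floor and had differences of 0.25 and 0.35.

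**Figure D1:**
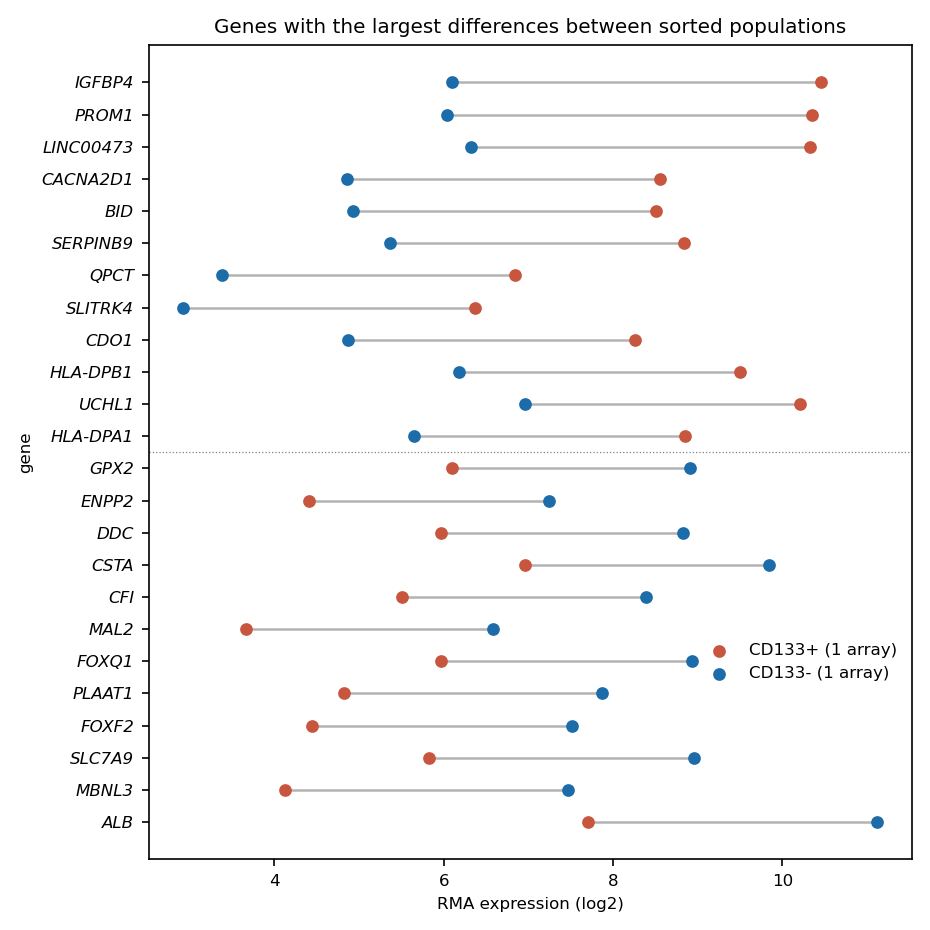
RMA expression on the log2 scale (horizontal axis) in CD133+ (red points) and CD133- (blue points), 1 array each, for the 12 counted genes with the largest difference in each direction, joined by a line per gene. The widest gaps are those of IGFBP4, at 4.36, and PROM1, at 4.32, on the higher side and of ALB, at -3.42, on the lower side.

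Among the genes lower in CD133+, ALB, which encodes serum albumin, was 10.7-fold lower, with differences from -3.42 to -2.69 over its probe sets above the floor. Its probe set left without the _x_at and _s_at ones was below the floor and had a difference of -0.22. SLC7A9, an amino acid transporter subunit, was 8.76-fold lower, the forkhead transcription factor FOXQ1 7.85-fold, complement factor I (CFI) 7.37-fold and the protease inhibitor CSTA 7.35-fold. DDC, the aromatic amino acid decarboxylase, and GPX2, a glutathione peroxidase, were 7.29-fold and 7.01-fold lower. The other probe set of DDC had a difference of -1.98, and that of GPX2 was below the floor. In 5 of the 12 genes the CD133+ value was under the floor. These were MBNL3, a splicing regulator, the forkhead factor FOXF2, PLAAT1, a phospholipid acyltransferase, MAL2, which acts in transcytosis in polarised cells, and ENPP2, which encodes autotaxin. Their RMA differences were -3.35, -3.07, -3.05, -2.92 and -2.83, and their MAS5 differences -3.73, -3.18, -2.51, -3.45 and -2.76. The other probe sets of MBNL3 were below the floor, and those of PLAAT1 and ENPP2 had RMA differences of -2.78 and -2.06.

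**Figure D2:**
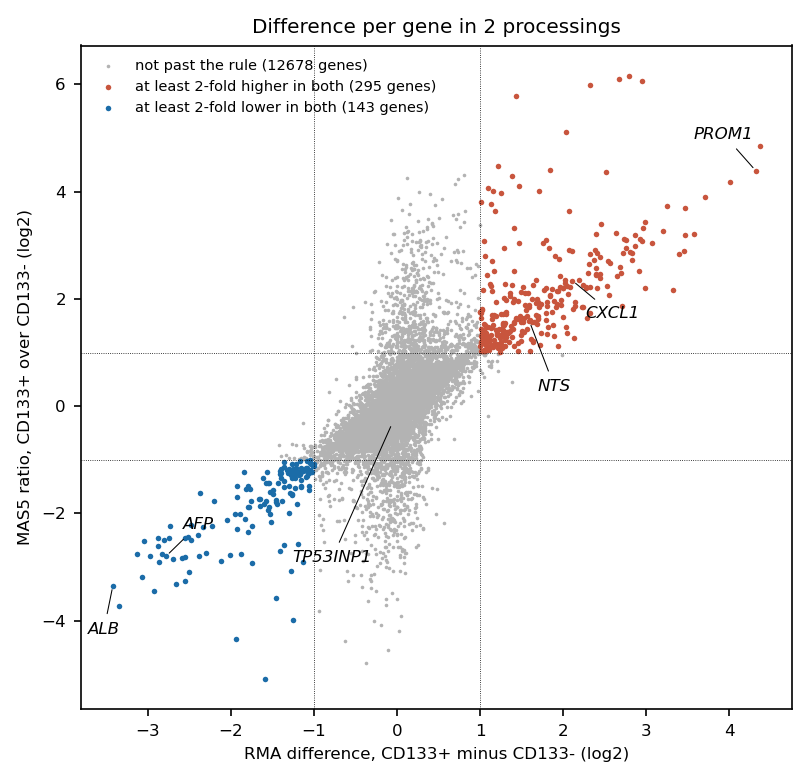
RMA log2 difference (horizontal axis) against MAS5 log2 ratio (vertical axis), CD133+ against CD133-, with 1 point per gene above the floor, the counted genes in red (higher) and blue (lower), and dotted lines at 2-fold. The 295 higher and 143 lower genes lie beyond 2-fold on both axes.

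The list of neurotensin, interleukin and CXC chemokine genes lay to the CD133+ side, through CXC chemokine genes and NTS. Of 13 members above the floor, 5 were counted as higher and none as lower, and 10 had a difference above 0. The list's median was 0.76, and none of the 10000 random lists had a median as high. NTS, CXCL8 and CXCL1, which earlier work on CD133+ liver tumour cells named, are members, so the list is not independent of that work. Left without them, in an alternative added after the values were seen, the list still stood apart from random lists. CXCL5, CXCL1 and CXCL3 were 6.60-fold, 4.31-fold and 3.11-fold higher. CXCL6, with a CD133- value under the floor, had differences of 2.94 in RMA and 3.08 in MAS5, and the fifth counted member was NTS. The other cytokine members IL1B, IL11, LIF and CCL20, chosen after their values were seen, had differences of -0.16, 0.20, -0.13 and -0.23 and were not counted. NF-kappaB targets had a median of 0.39, again above all random lists, with 4 of 17 members higher and none lower. The 4 were TNFAIP2, at 5.42-fold, CXCL1, LTB, which encodes lymphotoxin beta, at 3.46-fold in RMA and 8.52-fold in MAS5, and CXCL3. LTB's probe set left without the _x_at and _s_at ones was below the floor and had a difference of 0.39. Without those probe sets the list's median was 0.17, inside the central 95% of random lists. Of the 17 NF-kappaB targets 7 are also in other lists, and without those shared with the chemokine list the median was also 0.17 and inside that range.

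Notch ligands, receptors and targets had a median of 0.29, at percentile 99.9, with 14 of 17 members above 0 but none counted. Their largest differences were 0.81 for HES4, 0.80 for NOTCH3, 0.71 for DTX1 and 0.48 for HEYL. The list was inside the central 95% of random lists at 0.31 in MAS5 alone, where the median had not fallen and the range reached higher. It was also inside at 0.13 with the median over probe sets and at 0.12 without _x_at and _s_at probe sets. Secreted angiogenic factors and their regulators had a median of 0.26, at percentile 99.7, and 1 of 17 members was counted in each direction. PLAU, the urokinase gene, had differences of 1.40 in RMA and 3.32 in MAS5 with a CD133- value under the floor, while SERPINF1, which encodes the angiogenesis inhibitor PEDF, was 4.94-fold lower. FGF2 and ANGPTL4 had RMA differences of 0.73 and 0.69. The list was inside the range of random lists with the floor at the 75th percentile, at 0.26, and without _x_at and _s_at probe sets, at 0.26. In both the median was about that of the main setting, and it was the range of random lists that reached higher. Mesenchymal genes had a median of 0.22, at percentile 98.2, over 12 members that went both ways. This list was inside the range at 0.065 with the floor at the 75th percentile. It was also inside at 0.26 without _x_at and _s_at probe sets, where the median had not fallen and the range reached higher. VIM, which encodes vimentin, was 2.36-fold lower and was the one counted member. CDH2, which encodes N-cadherin, had an RMA difference of 1.99 and a MAS5 difference of 0.96, and COL5A2 one of 0.86 in RMA.

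The list of drug efflux and detoxification genes lay to the CD133- side, and its counted members were detoxification genes. Of 20 members, 3 were counted as lower and none as higher, 16 had a difference below 0, and the median was -0.51, below every random list. AKR1C3 and AKR1C2, aldo-keto reductases that act on steroids, were 6.49-fold and 2.88-fold lower, and SRXN1, which encodes sulfiredoxin, was 2.32-fold lower. AKR1C1 had differences of -1.18 in RMA and -0.98 in MAS5. These aldo-keto reductases are close in sequence, so their probe sets can share signal. AKR1C2's probe set left without the _x_at and _s_at ones was below the floor and had a difference of -0.63. None of the 7 ABC transporters above the floor, chosen as a group after their values were seen, was counted, and their differences ran from -0.67 for ABCB1 to 0.16 for ABCC4.

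Liver progenitor and tumour-initiating cell markers other than PROM1 also had a median below every random list, at -0.45, with 4 of 14 members lower and 1 higher. AFP, which encodes alpha-fetoprotein, was 6.86-fold lower, SPP1, which encodes osteopontin, 6.32-fold, and SOX9, a transcription factor of the biliary lineage, 2.90-fold. CD47 had a difference of -1.15 and was chosen after its values were seen. KRT19, a biliary keratin, was the higher one, with differences of 2.95 in RMA and 6.06 in MAS5 and a CD133- value under the floor. This list was inside the range of random lists at 0.00 with the median over all probe sets of a gene, at -0.056 with no floor and at -0.25 without _x_at and _s_at probe sets.

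Mature hepatocyte genes had a median of -0.23, which 4 of 10000 random lists reached, and 21 of 28 members were below 0. Besides ALB, the counted lower members were APOA1 at 3.48-fold, PCK1, a gluconeogenic enzyme, at differences of -2.52 in RMA and -2.45 in MAS5 with a CD133+ value under the floor, and APOC3 at an RMA difference of -1.17, which was chosen after its values were seen. RBP4, which encodes the plasma retinol carrier, was 3.09-fold higher. In MAS5 with a pseudocount of 50 the list's median was -0.087, and without _x_at and _s_at probe sets it was -0.064, both inside the central 95% of random lists. APOA1's probe set left without the _x_at and _s_at ones was below the floor and had a difference of -0.66. Fatty acid and lipid metabolism genes had a median of -0.34, which 4 random lists reached, with 1 of 17 members counted. MTTP, needed for lipoprotein assembly, was 2.42-fold lower, FABP1 had differences of -1.24 in RMA and -0.97 in MAS5, and ACSL1 and PLIN2 had RMA differences of -0.89 and -0.75. This list was inside the range in MAS5 alone, at -0.21, and in MAS5 with a pseudocount of 50, at -0.20.

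Cancer-testis antigens had a median of -0.41, which 2 random lists reached. MAGEB2 and MAGEC2 were 3.79-fold and 2.23-fold lower and were the counted members among 13, and PAGE1 and MAGEA1 had differences of -0.96 and -0.76. Of the 13 members, 7 lie in runs of neighbouring genes that differed together, and without these the median was -0.13, inside the central 95% of random lists. The list was also inside at -0.16 with the floor at the 75th percentile and at -0.034 without _x_at and _s_at probe sets. MAGEC2's probe set left without those was below the floor and had a difference of -0.13. Immediate-early and heat-shock genes had a median of -0.36, which 3 random lists reached, with none of 19 members counted. FOS, DUSP1, ATF3 and ZFP36 had differences of -0.90, -0.86, -0.63 and -0.61. Without _x_at and _s_at probe sets the list was inside the range, at -0.22.

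**Figure D3:**
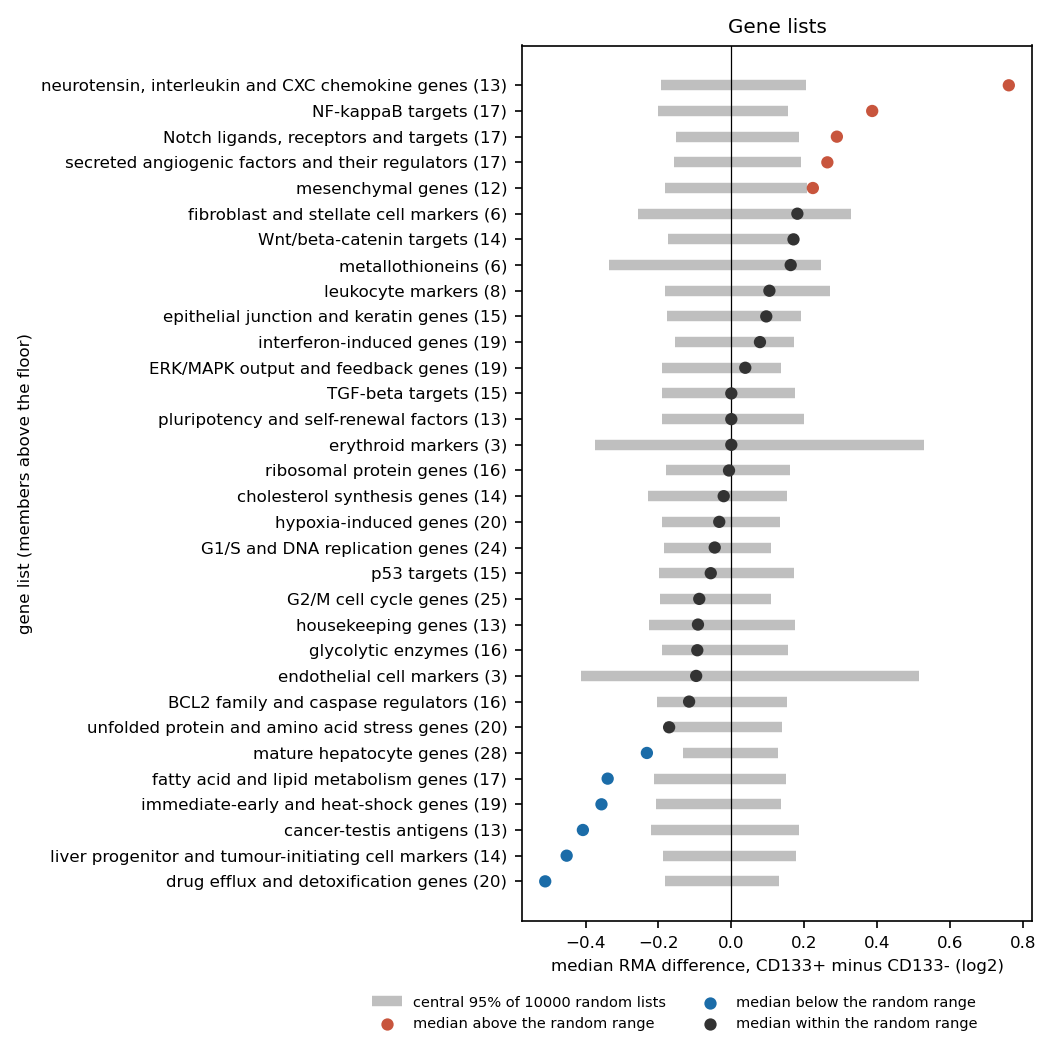
Median RMA log2 difference, CD133+ minus CD133-, of each of the 32 gene lists (points) with the central 95% of 10000 random lists matched on mean RMA value (bars). There are 5 lists above and 6 below their range, with neurotensin, interleukin and CXC chemokine genes at 0.76 and drug efflux and detoxification genes at -0.51 at the ends.

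In all, 11 of 32 lists stood apart from random lists, where 1.6 would do so by chance if the lists were independent, which lists with shared members are not. Random lists also hold unrelated genes, while genes of one list can vary together, so 11 against 1.6 does not measure an excess over chance. The remaining 21 lists did not stand apart in the main setting, and 6 of them did under an alternative. Proliferation genes were among the 21 lists but not among the 6. None of 24 G1/S and DNA replication genes and none of 25 G2/M cell cycle genes was counted, with medians of -0.05 and -0.09. CDK1 and KIF11 had differences of 0.69 and 0.68, and AURKA one of -0.61. Ribosomal protein genes had a median of -0.01, housekeeping genes -0.09 and metallothioneins 0.16, with no member counted. Cholesterol synthesis genes had a median of -0.02 and p53 targets of -0.06, also with none counted. Pluripotency and self-renewal factors had a median of 0.00, with STAT3 2.25-fold lower as the one counted of 13, and with a difference of -0.85 in another of its probe sets.

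Wnt/beta-catenin targets had a median of 0.17, at percentile 96.9, and 2 of 14 members were counted, DKK1, a Wnt antagonist, at 3.64-fold and BMP4 at 2.02-fold higher. This list stood apart at 0.31 with the floor at the 75th percentile, at 0.25 without _x_at and _s_at probe sets and at 0.30 without genes in shifted runs. TGF-beta targets had a median of 0.00, and 3 of 15 members were counted, TGFBI at 2.46-fold, LTBP1 at 2.08-fold and TGFB1 at 3.14-fold higher, although the other probe sets of LTBP1 and TGFB1 had differences of 0.61 and 0.28. ERK/MAPK output and feedback genes had a median of 0.04 with none of 19 counted, and DUSP5 had differences of 1.06 in RMA and 0.96 in MAS5. The list stood apart at 0.29 without _x_at and _s_at probe sets. Unfolded protein and amino acid stress genes had a median of -0.17, at percentile 3.24, with 3 of 20 lower: CTH at 2.56-fold, the cystine transporter SLC7A11 at 2.39-fold and TRIB3 at 2.13-fold. This list stood apart below random lists in 5 alternatives: -0.15 in MAS5 alone and with a pseudocount of 50, -0.20 with the floor at the 75th percentile, -0.23 without _x_at and _s_at probe sets and -0.16 without genes in shifted runs.

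Interferon-induced genes had a median of 0.08 with 2 of 19 higher, PSMB9, an immunoproteasome subunit, at 4.04-fold and MX2 at 2.03-fold. This list stood apart at 0.29 in MAS5 with a pseudocount of 50 and at 0.16 with the median over probe sets. Epithelial junction and keratin genes had a median of 0.10 with 2 of 15 higher and 1 lower. CDH1, which encodes E-cadherin, was 6.99-fold higher beside KRT19, with a difference of 1.28 in its other probe set, and MAL2 was the lower one. With the median over probe sets this list stood apart at 0.22. BCL2 family and caspase regulators had a median of -0.12, with BID as the one counted of 16, and stood apart at -0.20 with the median over probe sets. Glycolytic enzymes had a median of -0.09, and ENO2, the neuronal enolase, was the one counted of 16, at differences of 2.54 in RMA and 2.70 in MAS5 with a CD133- value under the floor. Hypoxia-induced genes had a median of -0.03 with 1 of 20 counted, CA12 at 2.25-fold higher, with differences from -0.18 to 1.65 over its probe sets.

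No list of markers of other cells stood apart from random lists. With 3 to 8 members above the floor their random ranges are wide, from -0.41 to 0.52 for endothelial cell markers. A moderate shift could therefore go unseen. Of 8 leukocyte markers above the floor, with a median of 0.10, LYZ alone was counted, at 3.31-fold higher. Fibroblast and stellate cell markers had a median of 0.18 over the 6 of 14 members above the floor, with none counted. LUM, below the floor and named after its values were seen, had differences of 2.53 in RMA and 3.16 in MAS5. The other members below the floor had smaller RMA differences in both directions. Erythroid markers had a median of 0.00 over 3. Of 3 endothelial cell markers above the floor, with a median of -0.10, PECAM1 was 3.38-fold lower, while its probe sets ran from -1.96 to 0.17.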

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

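Probe sets without a single gene name lie outside the comparison of genes, and 4758 of them were above the floor. By the count rule 40 were higher and 45 lower in CD133+. The largest difference on the higher side was 3.11, for a probe set with RMA values of 7.45 and 4.34, and on the lower side -3.55, for a probe set with values of 7.18 and 10.73 whose annotation lists several genes.

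The array's control probe sets lie outside the comparison as well. The 3 probe sets for 18S rRNA had a median RMA difference of 0.39, all higher in CD133+. The 18 probe sets of the hybridisation controls had a median of 0.13, and all 18 were higher in CD133+. The 24 poly-A spike-in probe sets had a median of -0.30, with 22 lower in CD133+, and the 2 probe sets for the 5' and middle parts of 28S rRNA one of -0.57.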

How the results depend on the processing

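Some alternatives were chosen after seeing the data. They left out genes in shifted runs, required a second probe set, or required a lower MAS5 value of at least 50. They also removed members shared between lists, or NTS, CXCL8 and CXCL1 from the chemokine list. No leave-one-out was possible with 1 array per population in each processing. No paired analysis was possible because the populations share no replicate beyond 1 array each per processing. PROM1 has only an _s_at probe set, so it has no value without such probe sets, and endothelial cell markers have none without genes in runs. The cause was not tested for any of the differences below, except that a stricter threshold or a smaller set of genes lowers a count by construction.

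The PROM1 difference ran from 4.16 to 4.39 over its alternatives. The counts of 295 higher and 143 lower genes were 923 and 601 in MAS5 alone, 698 and 547 at 1.5-fold, and 122 and 53 at 3-fold. With a second probe set that also differs 2-fold, 61 of 103 and 45 of 64 genes were left, and without genes in shifted runs 242 and 92. All other alternatives gave counts within 1.5 times, including 261 and 131 where the lower MAS5 value was at least 50. The correlation of RMA and MAS5 differences was 0.452 with no floor.

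Of 101 list medians under alternatives, for the 11 lists apart from random lists, 81 stayed apart in the same direction, 20 came to lie inside the central 95% and 0 reversed. Centring shifts a list and its random lists by the same amount, so by construction it could move no list into or out of the range. The medians for neurotensin, interleukin and CXC chemokine genes and for drug efflux and detoxification genes stayed apart under every alternative run. Without _x_at and _s_at probe sets the medians inside the range were 0.26 for angiogenic factors, -0.034 for cancer-testis antigens, -0.064 for hepatocyte genes, -0.22 for immediate-early genes, -0.25 for progenitor markers, 0.26 for mesenchymal genes, 0.17 for NF-kappaB targets and 0.12 for Notch genes. With the floor at the 75th percentile they were 0.26 for angiogenic factors, -0.16 for cancer-testis antigens and 0.065 for mesenchymal genes. In MAS5 alone they were -0.21 for lipid genes and 0.31 for Notch genes, and with a pseudocount of 50, -0.20 for lipid and -0.087 for hepatocyte genes. Progenitor markers were at -0.056 with no floor and 0.00 with the median over probe sets, where Notch genes were at 0.13. NF-kappaB targets without chemokine-list members were at 0.17, and cancer-testis antigens without genes in runs at -0.13. Of 178 medians for the other lists, 13 moved outside the range, in 6 lists: unfolded protein and amino acid stress genes, Wnt/beta-catenin targets, interferon-induced genes, ERK/MAPK genes, epithelial genes and BCL2 family genes. Of 1129 values of named genes, 1004 stayed within the spread between probe sets, and no counted gene changed sign. This share overstates stability, since dropping or raising the floor leaves a gene's value as it was by construction. Centring moves all values by the same small amount, and the median over probe sets cannot change a gene with a single probe set. Without _x_at and _s_at probe sets the counted genes MAGEC2, AKR1C2, APOA1, LTB and CA12 had differences of -0.13, -0.63, -0.66, 0.39 and 0.16. For MAGEC2, AKR1C2, APOA1 and LTB these values came from probe sets below the floor.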

Other observations

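The gene lists of the next paragraph, the tests of sorting stress, of cross-hybridising probe sets, of a gained chemokine segment and of the share of counted genes in runs were chosen only after the result was seen. The lists of MHC class I processing genes, of other MHC class II genes and of abundant leukocyte genes were written after HLA-DPA1 and HLA-DPB1 were seen and before the values of their members were, except those of B2M, PSMB9, PTPRC, TYROBP, LAPTM5 and CD53, which the lists fixed beforehand also hold.

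Among the genes with large differences were groups that no list fixed beforehand held. Of 16 neuronal and neuroendocrine genes above the floor, 8 were counted as higher in CD133+, among them NMB, TUBB2B and INA with differences of 2.75, 2.73 and 2.06. The list was written after 6 of the 16 had been seen among the large differences, and these 6 are part of the 8. DNER and NPW, with CD133- values under the floor, had differences of 2.98 and 2.67 in RMA and 3.43 and 6.10 in MAS5. The 10 members whose values had not been seen when the list was written had a median of 0.30, at percentile 99.2. Of 15 genes of caveolae and the actin cytoskeleton, 4 were counted as higher, and these were the 4 already seen when the list was written. CSRP1, CAV1 and CAV2 had differences of 2.75, 2.56 and 2.45, and MYL9, with a CD133- value under the floor, 2.51 in RMA and 4.36 in MAS5. The 11 members not seen had a median of 0.45. Complement and acute phase genes of the liver mostly ran the other way. Of 21 members, 3 of them seen before the list was written, 16 were below 0 and 4 were counted as lower, among them LBP at -2.50, F12 at -2.05 and HPX at -1.21. F10, at 1.02, was counted as higher, and C3 had a difference of 0.85. The 18 members not seen had a median of -0.37, below every random list. The S100 genes went both ways, with S100A11 at 2.64, S100A9 at -2.48 and a median of 0.03 over 11. All genes in this paragraph were chosen after their values were seen.

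HLA-DPA1 and HLA-DPB1 had RMA differences of 3.21 and 3.32, and of the genes near them PSMB8, PSMB9 and HLA-DMA had 2.32, 2.01 and 0.66, with HLA-DMB 2.84-fold higher, while HLA-DOA and COL11A2, next to them, had 0.32 and 0.28 and BRD2 -0.36, named after their values were seen except PSMB9. Leukocytes in the CD133+ preparation would bring CD74 and HLA-DRA at least as strongly, but the higher of their RMA differences was 0.084, and HLA-DRA and PTPRC were below the floor, although CD74 had a MAS5 difference of 2.24 at intensities of 89.6 and 19.0, against 2163 for HLA-DPA1 in CD133+. Of 7 abundant leukocyte genes, with a median of 0.12, ARHGDIB, named after its values were seen, was counted as higher, at 1.14 in RMA and 2.70 in MAS5 with a CD133- value under the floor, as was LYZ among the leukocyte markers. A response of the whole class II group through CIITA by 2-fold or more does not match the median of 0.25 over the 8 other members or the difference of -0.05 for CIITA, but that median lies at percentile 98.2, so a smaller shift of the group stays open, as does one of the 13 genes of MHC class I processing, with a median of 0.34 at percentile 99.96. A hypothesis that stays open too is regulation of part of this region, which may differ between the populations, and no value here tests it.

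The CXCL genes higher in CD133+ lie in one cluster on chromosome 4, where 6 CXCL genes above the floor had a median difference of 1.87 and PF4, a CXC chemokine gene among them that was left out of this median, had 1.79. A stress response to sorting, which both populations underwent, would have to be stronger in CD133+ and raise immediate-early and heat-shock genes there. Their median was -0.36, a value already seen when this test was chosen. It tells only that these genes were not raised in CD133+ when RNA was taken. Without _x_at and _s_at probe sets the list's median was 1.59 over 9 members. That is the value of NTS, which is no chemokine, so this median does not test whether chemokine probe sets hybridise to several chemokines. CXCL6, CXCL1 and CXCL3 each have 1 probe set, which ends in neither, and had differences of 2.94, 2.11 and 1.64. The probe sets that represent CXCL5 and CXCL8 end in _x_at, so for them shared signal stays open. All 3 probe sets of CXCL5 were above the floor, with differences from 2.72 to 3.15, and the 2 of CXCL8 had 0.93 and 1.52. A gained segment that raised the neighbours as much as the cluster does not match the 10 expressed genes on each side, which had a median of 0.16. Of these 20 genes 7 were below 0, among them ALB and AFP, close to CXCL8 on one side, at -3.42 and -2.78. The genes next to the cluster, RASSF6 and MTHFD2L, named after their values were seen, had 0.43 and 0.66. A smaller gain, or one confined to the cluster, is not excluded by these values. Regulation of the cluster as a whole and of its genes singly both stay open and were not tested.

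Genes that neighbour each other on a chromosome differed together. The largest median over 50 neighbouring genes was 0.55 in size, against 0.19 in the median of 1000 random orders of 13085 genes and 0.27 in the highest, and it stayed at 0.57 with trends on level and gene length subtracted and at 0.48 without the counted genes, so neither a trend nor a few strong genes accounts for a largest window of this size. The other runs were not tested in this way, and the weakest, at -0.23, lies close to the 0.23 that 95% of random orders stay under. There were 20 runs, 14 lower and 6 higher in CD133+, all with the same sign in MAS5. The highest were on chromosome 13, from POLR1D to GAS6, where 46 of 50 genes of the strongest window were above 0, on chromosome 11, from MRPL49 to DHCR7, at 0.53, and on chromosome 7, from NUDCD3 to MKLN1, at 0.46. The lowest were on chromosome X, from NUP62CL to TMEM187, at -0.49, and on chromosome 5, from HBEGF to TRIM52-AS1, at -0.47.

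A candidate explanation of the runs is that the sorted populations differ in the copy number of chromosome segments, as separate subclones of the line would, and no random order reached 0.55. Regulation over whole regions and GC content, which could not be tested without a genome, stay open. Of the counted genes 23.7%, 104 of 438, lie in the runs, against 18.1% of all placed genes. A copy number difference over these runs would therefore leave most counted genes unexplained. Segments much shorter than a window, or with a smaller shift, can escape the search for runs. The share in runs thus cannot decide on copy number for the counted genes outside them. By direction 51 of 143 lower and 53 of 295 higher genes lie in runs. Lower runs held 32.9% of the lower genes and 12.1% of placed genes, and higher runs 12.9% of the higher and 6.2% of placed genes. The runs were found from the same differences that set the counts, so by construction counted genes fall more often in runs of their own direction. This excess is therefore no support for copy number, which stays open for the counted genes in the runs and was not tested for those outside them. The strongest window of each run had a median shift between 1.18-fold and 1.46-fold. A shift of that size alone would leave a gene under the 2-fold of the count rule. Noise of single probe sets does not account for the 167 counted genes with a second probe set above the floor, since in 89.8% of them it was past the probe set spread in the same direction, against 23.1% of the other genes, and the remaining counted genes have no such check.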
